A study of Homo sapiens with 8 samples.

How the data were processed

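ChIP-seq for H3K27ac, with a paired input library, was made from MV4-11, MV4-11-MITR, OCI-AML3 and OCI-AML3-MITR cells, 8 samples in all. Each of the 4 H3K27ac libraries had a peak list. The 4 input libraries had no file and entered no result here. Per the labels, chromatin was immunoprecipitated, the DNA was tagmented with Tn5 and amplified over 12 to 15 PCR cycles, and fragments of about 250 bp were selected. The labels call every sample untreated, while the shared protocol text describes a 16 h treatment with 100 nM of the BRG1/BRM inhibitor FHD-286 and the design text a 16 h treatment with a Menin inhibitor. The samples are taken here as untreated, as their own labels say. Groups were taken from the sample titles. The library name of MV4-11-MITR reads VTPR in place of MITR and the growth protocol names 2 other AML lines, so the identity of the lines rests on the titles.

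The submitters' processing notes name bcl2fastq 2.17, Trimmomatic 0.33, Bowtie 1.1.2, MACS2 2.1.0, deepTools and the GRCh38 (hg38) build, with no settings. The files have the layout of broad regions from MACS2, and there is 1 per H3K27ac library, so peaks were called per library. Whether the input served as control, how duplicates were treated and how deep the libraries were sequenced are not given in the sources used here. A deeper or cleaner library yields more and longer peaks, and Tn5 and PCR can favour some DNA over other DNA, so a missing peak can reflect calling as well as chromatin.

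Each deposited peak carries the authors' score, which equals the −log10 q value times a fixed factor and was not used. It carries the authors' fold enrichment, a ratio of signal to the caller's background within that library. It also carries the authors' deposited −log10 p and −log10 q values, averaged over the region and not normalized between libraries. These values are the authors' own and were used only to describe, rank or filter peaks within a list. The lowest −log10 q in the lists was 1.00. Peaks on chromosomes 1 to 22 and X were used and other sequences were not analysed here.

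From the coordinates the covered length (overlapping peaks merged), the Jaccard index of covered base pairs for each pair of lists, and the quantities below were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Figures used matplotlib 3.10.9. Gene positions came from a RefSeq gene table of assembly GRCh38.p14, the build of the files, with 19970 protein-coding genes on these chromosomes. The table gives neither strand nor transcripts. The design fixed before the data were examined had called for annotated transcript starts; instead, a promoter was counted as marked when a peak overlapped, by at least 1 bp, the window of 1 kb either side of either end of the gene. A mark at a gene's 3′ end therefore counts too, and an internal start such as those of MEF2C does not. Gained means marked in the MITR list and not in the parent list, lost the reverse. Distal peaks lay more than 2 kb from both ends of 38147 protein-coding and long noncoding genes. A distal region was gained or lost when no base pair of it lay in a peak of the other list.

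Peaks within 10 kb of each other were stitched, domains were ranked within a list by the sum of fold enrichment times width, and the top 500 per list were compared. Each domain was named for the protein-coding gene with an end in it or nearest to it. For each gene the acetylated length was the length covered by peaks in the gene body with 20 kb each side. Its change was log2 of the MITR length plus 500 bp over the parent length plus 500 bp, less the log2 ratio of the total covered lengths (−0.10 in the MV4-11 pair and −0.42 in the OCI-AML3 pair). A gene is called longer above 1 and shorter below −1. This is a rule of size and not a test, since there was 1 library per group. Windows of neighbouring genes overlap, so genes are not independent. A depth-based error cannot be given for a peak list. Wilson intervals at 95% are given for shares of domains and cover counting error only.

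The 23 gene lists (535 members, all matched, with GLTSCR1L read as BICRAL and DDX58 as RIGI) were fixed before the data were examined. They are the MLL and Menin target genes, HOXB genes, Menin and MLL complex and cofactors, BAF complex, BET proteins and elongation, Polycomb group, monocyte and macrophage markers, neutrophil and granule markers, stem and progenitor genes, myeloid transcription factors, BCL2 family, drug transport and xenobiotic genes, antigen presentation, interferon response, inflammatory and NF-kB genes, cytokine receptors and signalling, WNT signalling, cell cycle regulators, T and NK cell, B cell, erythroid and megakaryocyte, and epithelial and neural markers, and housekeeping genes. The median change of a list was placed among 10000 random lists of the same size matched on mean acetylated length. In addition, chosen after seeing the data, random genes were matched on gene density within 500 kb. A list whose median equals or adjoins the value of a gene with no peak in either list says little by its percentile, since random medians pile up there.

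The named genes were fixed by rule. They include MEN1, KMT2A, HOXA9, MEIS1, SMARCA4, SMARCA2, MYC, CDK6, BCL2 and FLT3; per line the 10 gained and 10 lost promoters with the highest fold enrichment among those with no peak of the other list within 10 kb, 1 gene per peak; up to 10 gained and 10 lost in both lines, by the lower fold percentile; the 5 highest domains of each list that overlap no top domain of the other; and the members of each list with the largest changes. Some genes that met these rules, and the tests of 1 pattern, are not reported here. For promoters gained or lost in both lines the number that independent lists would share was computed from the genes able to pass both criteria, and for acetylated length, after seeing the data, from the genes with a peak in at least 1 list of each pair.

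The settings varied were equal numbers of peaks, equal covered length, a −log10 q of at least 5, autosomes only, other windows, overlaps, stitching and ranking rules, another pseudo-length and flank, and no scaling. The 5 other settings for single genes were a pseudo-length of 2000 bp, flanks of 5 kb, flanks of 50 kb, no scaling and equal numbers of peaks. A count by the gene's 5′ end alone and a motif search in distal regions belonged to the design and were not run here, for lack of strand and sequence. The functions were tested on simulated data: in each parent's list 200 promoters were marked and 200 emptied among the 19970 genes, and 100% of both kinds were recovered in both lines. The planted changes met the marking rule by construction and held no noise of depth or calling. This checks the code and not how reliable the reported gains and losses are.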

Results

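H3K27ac, a histone acetylation mark of active promoters and enhancers, was mapped by ChIP-seq in 4 human acute myeloid leukaemia (AML) cell populations. MV4-11 carries a rearranged KMT2A (MLL1) gene and OCI-AML3 a mutant NPM1 gene, and both kinds of AML depend on Menin, the MEN1 product that tethers the KMT2A complex to chromatin. The remaining populations, MV4-11-MITR and OCI-AML3-MITR, are taken from the sample titles as sublines of these lines, although the library name of MV4-11-MITR reads VTPR in place of MITR. The labels do not spell out MITR, while the series title names resistance to Menin inhibitors. All samples carry an untreated label, so the design compares the resting H3K27ac landscape of each MITR line with that of its parent. Each population had 1 H3K27ac library, so no value below has a replicate error and no test or p-value is given. Differences describe these libraries and not the lines at large.

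The peak lists held 54257 peaks over 212.1 Mb in MV4-11, 61943 over 198.6 Mb in MV4-11-MITR, 75780 over 202.8 Mb in OCI-AML3 and 67086 over 151.6 Mb in OCI-AML3-MITR (chromosomes 1 to 22 and X). The MITR list thus had 1.14 times as many peaks as its parent's in MV4-11 and 0.885 times as many in OCI-AML3, and covered 0.936 and 0.747 times the length. With peaks of −log10 q of at least 5 alone, MV4-11-MITR had fewer peaks than MV4-11 (11222 against 11612). Promoter windows were marked for 10911, 11573, 11893 and 11810 of 19970 protein-coding genes, in the order above. All 20 housekeeping genes of a fixed list, among them ACTB, GAPDH and POLR2A, were marked in all 4 lists. Sequencing depth is unknown for these files, and list size depends on it.

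The first comparison asked how much of the landscape each MITR line shared with its parent. MV4-11 and MV4-11-MITR shared 145.4 Mb, a Jaccard index (shared over combined length) of 0.548, and the OCI-AML3 pair shared 123.2 Mb, an index of 0.533. The parents shared less with each other, at 0.378, and the MITR lines least, at 0.304. Peaks near gene ends were shared more than distal peaks, at 0.558 against 0.379 in the MV4-11 pair and 0.593 against 0.398 in the OCI-AML3 pair. Peaks were also split into 4 equal parts by the authors' fold enrichment. In the highest part 95.8% of the peaks of MV4-11-MITR and 98.1% of those of OCI-AML3-MITR overlapped a peak of the parent, against 30.8% and 51.8% in the lowest. Of the parents' peaks 93.0% in the highest part of MV4-11 and 96.4% in that of OCI-AML3 overlapped a peak of the MITR list, but in MV4-11 the share did not rise steadily, with 58.2, 43.4 and 58.1% in the parts below, from the lowest up.

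**Figure D1:**
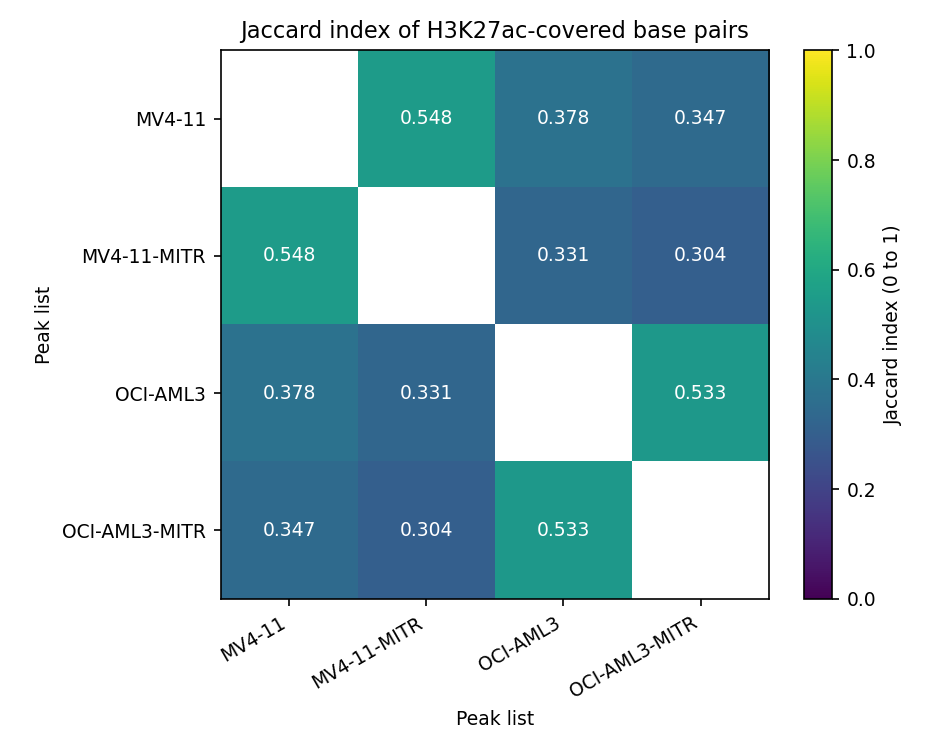
Jaccard index of base pairs covered by H3K27ac peaks (0 to 1, colour and printed value) for each pair of the 4 peak lists, 1 library each. Each MITR list is closest to its own parent (0.548 and 0.533), above the index of the parents (0.378).

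The genes named by the study's subject differed between the lines. MEIS1, a HOX cofactor and Menin-dependent leukaemia gene (chromosome 2, 66435125 to 66573869, GRCh38), had 60.5 kb of acetylated length in MV4-11 and 18.9 kb in MV4-11-MITR, a scaled log2 change of −1.55. In OCI-AML3 it had 31.7 kb, and OCI-AML3-MITR had no peak over the gene or within 20 kb of it (log2 change −5.59). MEF2C, a myeloid transcription factor gene in the same programme, had 80.3 kb in MV4-11 and 1.04 kb in MV4-11-MITR (−5.62), against 62.4 and 35.4 kb in the OCI-AML3 pair (−0.39). PBX3, another HOX cofactor, had 41.3 and 15.1 kb in the MV4-11 pair (−1.33) and 22.5 and 11.5 kb in the OCI-AML3 pair (−0.53). HOXA9 went from 12.9 to 24.5 kb in MV4-11-MITR (0.99) and from 34.4 to 30.3 kb in OCI-AML3-MITR (0.24), inside the size rule in both, though past it in MV4-11-MITR with 50 kb flanks (2.03) and with equal numbers of peaks (1.03). With equal covered length in all lists, the MEIS1 change in MV4-11-MITR was −0.97, just inside the rule.

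Among the other genes followed by name, BCL2, the antiapoptotic target of venetoclax, was shorter in OCI-AML3-MITR (159.2 to 56.3 kb, −1.07) and nearly level in MV4-11-MITR (154.8 to 143.3 kb, −0.02). FLT3, a receptor kinase gene, went from 97.6 to 72.1 kb (−0.34) and from 38.5 to 19.6 kb (−0.54). CDK6, a cell cycle kinase gene, went from 235.7 to 183.7 kb (−0.26) and from 232.6 to 132.7 kb (−0.39). MYC changed by −0.31 (11.57 to 8.61 kb) and 0.11 (20.12 to 16.15 kb). SMARCA4 (BRG1) had 27.4 and 44.0 kb in the MV4-11 pair (0.77), whereas SMARCA2 (BRM) was shorter in MV4-11-MITR (16.8 to 6.52 kb, −1.20). In OCI-AML3-MITR SMARCA4 changed by 0.40 (20.85 to 20.53 kb) and SMARCA2 by 0.37 (20.19 to 19.53 kb). A scaled value can thus be positive where the length fell. The median scaled change of genes with a peak was 0.16 in MV4-11-MITR and 0.28 in OCI-AML3-MITR, so 0 is not the typical value. MEN1 changed by 0.62 and was longer in OCI-AML3-MITR (3.16 to 5.51 kb, 1.14). KMT2A changed by 0.61 in MV4-11-MITR and was shorter in OCI-AML3-MITR (12.4 to 4.18 kb, −1.04). MEN1, KMT2A and BCL2 in OCI-AML3-MITR lay close to the size limit of 1. MEN1 was inside it under 3 of 5 other settings, at 0.31 in the lowest, and KMT2A and BCL2 each under 1 of 5. SMARCA2 in MV4-11-MITR changed by −0.46 with 50 kb flanks.

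**Figure D2:**
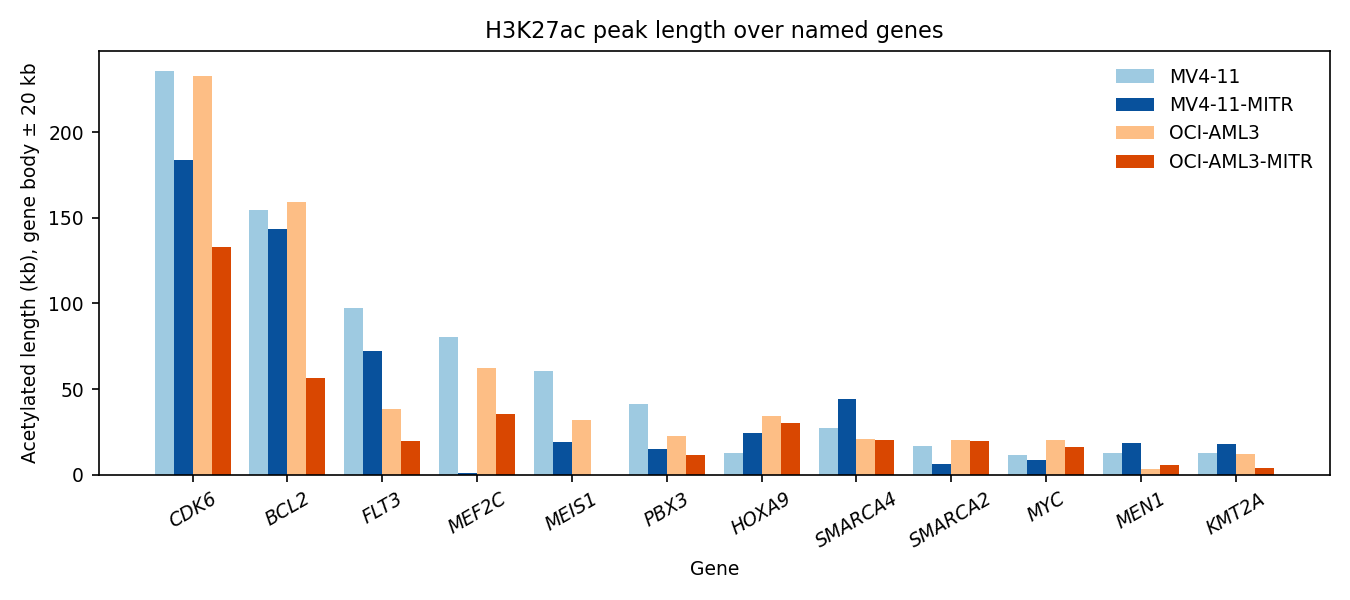
Acetylated length in kb (bars, gene body with 20 kb each side) of 12 genes in the 4 peak lists, 1 library each, so no error is drawn. MEF2C stands at 1.04 kb in MV4-11-MITR and MEIS1 has no bar in OCI-AML3-MITR.

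The MLL and Menin target list moved in opposite directions within MV4-11-MITR. Of its 30 genes, 9 were longer and 6 shorter. The longer genes all lay in the HOXA cluster on chromosome 7, among them HOXA4 (0 to 11.7 kb), HOXA5 (1.93 to 13.6 kb) and HOXA13 (0.603 to 27.5 kb). Their windows overlap, so they are not separate events. The shorter genes were MEF2C, SENP6, TCF4, MEIS1, PBX3 and JMJD1C, the last from 131.1 to 53.1 kb. In OCI-AML3-MITR 2 members were longer and 4 shorter (0 and 6 without scaling). MEIS1, SENP6 (29.5 to 9.24 kb), RUNX2 (113 to 39.1 kb) and BCL2 were the shorter ones, so MEIS1 and SENP6 were shorter in both lines, though SENP6 in OCI-AML3-MITR came to −0.99 under 1 other setting. HOXA2, among the longer ones, rested on 1 peak of 0.811 kb in the parent and 1.51 kb in the MITR line, and passed the rule under none of 5 other settings. The list median lay at percentile 0.65 of matched random lists in MV4-11-MITR and 5.43 in OCI-AML3-MITR, and at 21.5 and 21.8 when random genes were also matched on gene density. Where no percentile is given for a list below, its median lay inside the central 95% of lists matched on length or within 0.01 of the value of a gene with no peak. Over all 19970 protein-coding genes, 15% were longer and 10% shorter in MV4-11-MITR, and 7% and 6% in OCI-AML3-MITR. These shares include genes with no peak. Counts of longer and shorter list members were not tested against them, so a count near these shares does not set a list apart.

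HOXB genes differed between the lines. In MV4-11-MITR 4 of 10 were longer, with HOXB2 at 0 and 12.6 kb and HOXB3 at 4.58 and 23.1 kb, and 1 was shorter (HOXB7, 2.33 to 0 kb, but 1.82 on the log2 scale with 50 kb flanks). Promoter marks there went the other way, from 3 in MV4-11 to 1 in MV4-11-MITR, with that of HOXB3 among those lost. In OCI-AML3, where 9 HOXB promoters were marked, none was longer in the MITR line and 2 were shorter (5 without scaling), with HOXB2 at 26.4 and 6.72 kb and HOXB9 at 20.2 and 6.48 kb. The list median was at percentile 98.4 in MV4-11-MITR (93.4 with gene density matched) and 0.01 in OCI-AML3-MITR, but most windows of these neighbours overlap, so a comparison with scattered genes overstates how far the list stands out.

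**Figure D3:**
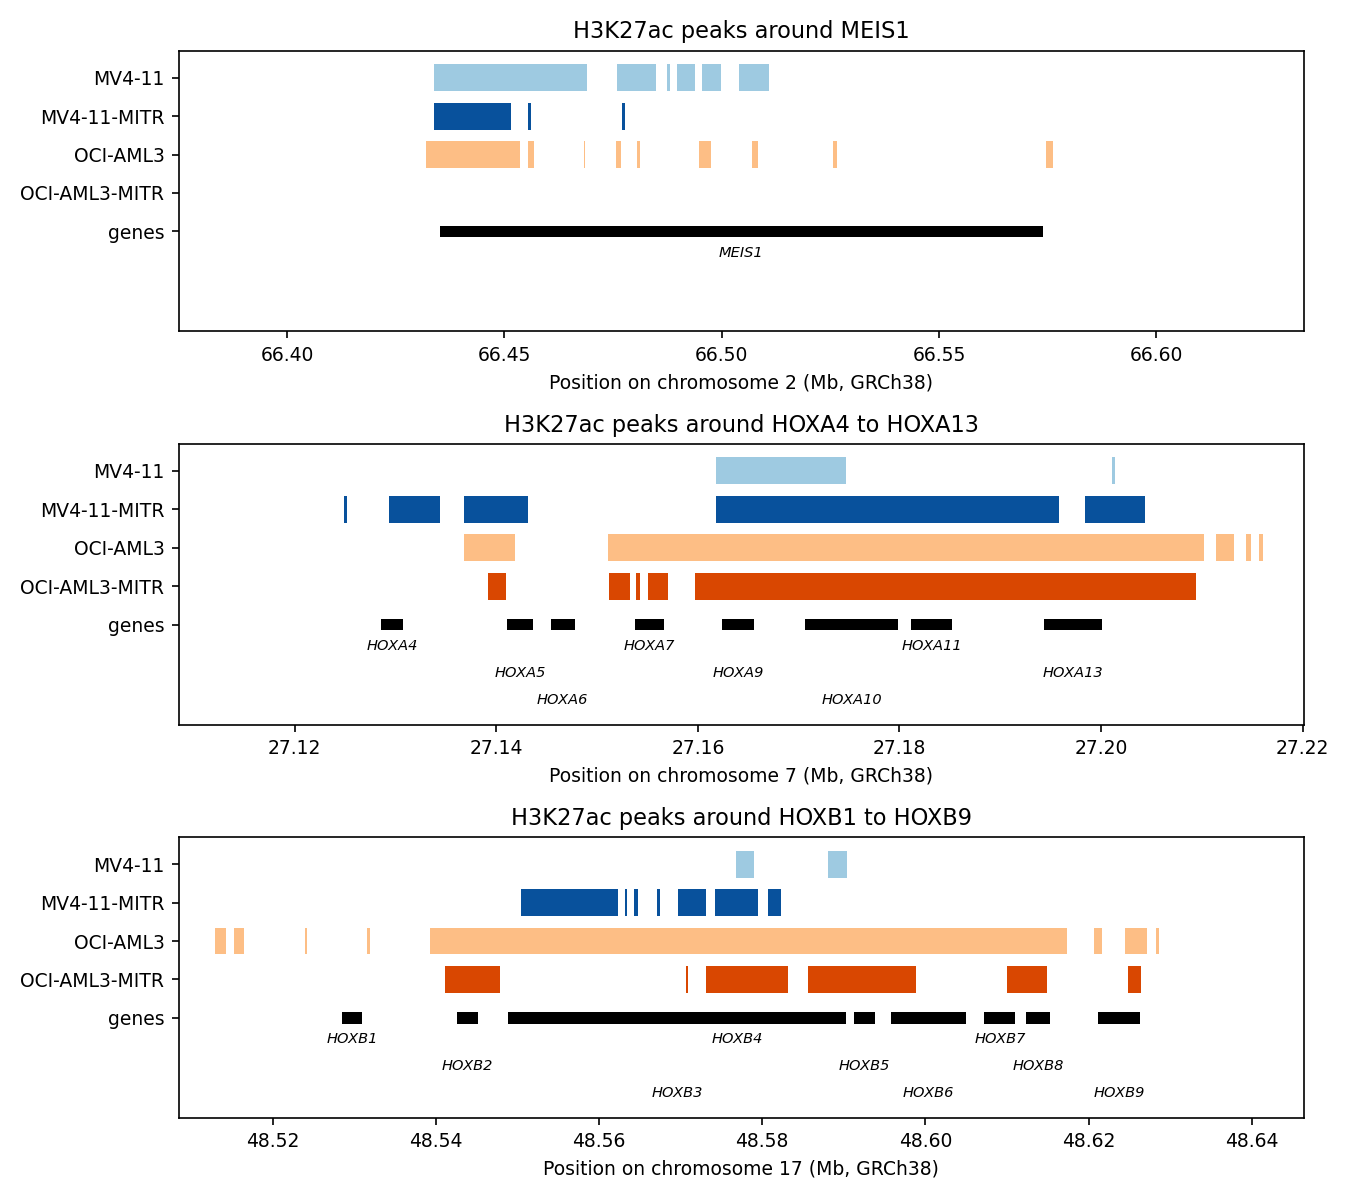
Positions of H3K27ac peaks (coloured boxes, 1 row per peak list) and genes (black boxes) around MEIS1 on chromosome 2, HOXA4 to HOXA13 on chromosome 7 and the HOXB cluster on chromosome 17, in Mb of GRCh38. OCI-AML3-MITR has no peak at MEIS1, MV4-11-MITR has a peak at HOXA4 where MV4-11 has none, and OCI-AML3-MITR keeps part of the HOXB domain of OCI-AML3.

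Of 23 genes for the Menin and MLL complex and its cofactors, 1 was longer and 2 shorter in MV4-11-MITR (1 and 3 without scaling): MLLT3 (0 to 5.0 kb), RBBP5 (21.4 to 6.24 kb) and MLLT10 (14.7 to 4.64 kb). In OCI-AML3-MITR only MEN1 and KMT2A passed the rule (0 longer and 3 shorter without scaling). Of 27 BAF complex genes, 5 were longer and 2 shorter in MV4-11-MITR (3 and 2 without scaling), and 3 longer and 2 shorter in OCI-AML3-MITR (2 and 3 without scaling). BICRA (4.66 to 13.8 kb, and 6.06 to 11.0 kb) and SMARCD1 were longer in both. The call of SMARCD1 in MV4-11-MITR was lost under 3 of 5 other settings, turning to −1.01 with 50 kb flanks. ARID1B (64.9 to 13.9 kb) and ARID2 (36.6 to 7.46 kb) were shorter in OCI-AML3-MITR. Of 15 genes for BET proteins and transcription elongation, 1 was shorter in each line, MED1 in MV4-11-MITR (31.3 to 10.9 kb) and MED12 in OCI-AML3-MITR (11.5 to 1.88 kb, but a log2 change of 0.38 with 5 kb flanks). Of 21 Polycomb group genes, 4 were longer and 1 shorter in MV4-11-MITR (3 and 2 without scaling), with CBX7 at 2.39 and 19.2 kb and EED at 3.84 and 1.08 kb. In OCI-AML3-MITR 1 was longer, SUZ12, at a change of 1.08 and inside the rule under 4 of 5 other settings (0 longer and 1 shorter without scaling), and the list median lay at percentile 97.4, or 98.5 with gene density matched.

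Of 25 monocyte and macrophage markers, 4 were shorter and 2 longer in MV4-11-MITR. CD36, a scavenger receptor gene, went from 24.2 to 6.2 kb and CD86, a costimulatory receptor gene, from 34.1 to 15.6 kb; CD163, a haemoglobin scavenger receptor gene, went from 0 to 1.48 kb. Under 2 of 5 other settings each, CD86 and CD163 lay inside the rule. The list median lay at percentile 0.49, and at 0.05 with gene density matched. In OCI-AML3-MITR 3 were longer and none shorter (1 and 1 without scaling), among them LYZ, encoding lysozyme (14.9 to 27.6 kb), and ITGAM, encoding CD11b (13.4 to 20.6 kb, inside the rule under 4 of 5 other settings). The median there lay at percentile 88.9, and at 80.5 with gene density matched. Of 20 neutrophil and granule markers, 2 were longer and 3 shorter in MV4-11-MITR, with the granule genes LTF (0 to 7.99 kb) and LCN2 (0 to 8.40 kb) longer and the formyl peptide receptor gene FPR2 shorter (25.6 to 8.02 kb), and a median at percentile 26.95 (3.78 with gene density matched). In OCI-AML3-MITR 3 were longer and 1 shorter (1 and 1 without scaling), with FPR1 at 10.3 and 23.3 kb, FPR2 at 5.98 and 11.7 kb and MMP8 at 4.80 and 0.971 kb, and a median (0.43) next to the value of a gene with no peak.

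Of 25 stem and progenitor genes, 3 were longer and 3 shorter in MV4-11-MITR, and 3 longer and 6 shorter in OCI-AML3-MITR (2 and 7 without scaling). ERG, an ETS factor gene of stem cells, was shorter in both lines (39.3 to 9.29 kb, and 20.6 to 4.64 kb, the latter at −0.95 under 1 other setting), and GATA2 was longer in both (0 to 3.35 kb, and 1.21 to 3.34 kb). In OCI-AML3-MITR PROM1, encoding CD133, went from 14.3 to 0 kb, TAL1 from 19.2 to 4.23 kb and KIT from 2.32 to 0 kb. Of 32 myeloid transcription factor genes, 5 were longer and 3 shorter in MV4-11-MITR (4 and 4 without scaling), with FOSB at 2.96 and 26.8 kb, CEBPB at 7.74 and 19.4 kb and BACH1 at 22.6 and 5.13 kb. In OCI-AML3-MITR 3 were longer and 1 shorter (1 and 2 without scaling), with KLF2 at 28.2 and 7.81 kb.

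Of 17 BCL2 family genes, 3 were longer and 1 shorter in MV4-11-MITR (3 and 2 without scaling), with the proapoptotic genes BOK (0 to 9.71 kb), BAK1 (8.26 to 19.2 kb) and BBC3 (15.1 to 32.5 kb) longer and another proapoptotic gene, HRK, shorter (5.89 to 2.24 kb, inside the rule under 3 of 5 other settings). In OCI-AML3-MITR BCL2 and BCL2L11, which encodes the proapoptotic protein BIM (52.0 to 7.35 kb), were the 2 shorter members and none was longer. Of 30 genes of drug transport and xenobiotic metabolism, 3 were longer and 6 shorter in MV4-11-MITR (2 and 7 without scaling), and 2 longer and 6 shorter in OCI-AML3-MITR (1 and 9 without scaling). ABCB1, the multidrug efflux pump gene, was shorter in both lines (3.45 to 0.380 kb, and 4.32 to 0 kb), each inside the rule under 1 of 5 other settings. The OCI-AML3-MITR median of this list lay at percentile 0.05.

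Among 19 antigen presentation genes, 5 were shorter and none longer in MV4-11-MITR, with the neighbouring MHC class II genes HLA-DQA1 (9.26 to 0 kb), HLA-DQB1 (8.64 to 0 kb) and HLA-DPA1 (4.09 to 1.27 kb) among the shorter ones. The list median lay at percentile 24.8, and at 0.85 with gene density matched, a choice made after seeing the data. In OCI-AML3-MITR none passed the rule and the median (0.42) lay just above the value of a gene with no peak. HLA genes are highly polymorphic and some have close paralogs, so reads can be misplaced and single HLA values are uncertain. Of 28 interferon response genes, 3 were longer and 3 shorter in MV4-11-MITR (IFIH1, IFI44 and IFI44L), and 4 longer and none shorter in OCI-AML3-MITR (3 and 1 without scaling), with the antiviral genes ISG15 (4.18 to 13.8 kb, and 2.64 to 6.23 kb), OAS1 and RIGI longer in both. Under 1 other setting ISG15 in both lines and OAS1, IFI44 and IFI44L in MV4-11-MITR lay inside the rule. IFI44 and IFI44L are neighbours with overlapping windows, each with 0.959 kb in MV4-11 and 0 in MV4-11-MITR, so they are not separate events. Of 26 inflammatory and NF-kB genes, 4 were longer and 1 shorter in MV4-11-MITR, with ICAM1 at 14.4 and 38.8 kb and REL at 18.7 and 6.36 kb. In OCI-AML3-MITR only CCL20 was shorter (27.1 to 7.14 kb; 3 shorter without scaling), with a list median at percentile 2.1. Of 36 cytokine receptor and signalling genes, 4 were longer in MV4-11-MITR, with STAT5A at 5.60 and 18.1 kb and DUSP4 at 0.278 and 13.3 kb. In OCI-AML3-MITR 2 were longer and 4 shorter (0 and 6 without scaling), with PIM1 at 4.72 and 9.21 kb and CSF2RB at 8.91 and 2.08 kb.

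Of 25 WNT signalling genes, 1 was longer and 1 shorter in MV4-11-MITR (TCF7L1 and GSK3B), and 5 longer and 1 shorter in OCI-AML3-MITR (3 and 2 without scaling), with FZD1 at 1.65 and 6.25 kb. Of 26 cell cycle regulators, 5 were longer and 3 shorter in MV4-11-MITR, and 3 longer and 1 shorter in OCI-AML3-MITR (0 and 2 without scaling). CDK4 was longer in both (7.36 to 21.6 kb, and 8.80 to 16.4 kb). CDKN2C, a CDK inhibitor gene, was longer in MV4-11-MITR (4.47 to 27.7 kb) and shorter in OCI-AML3-MITR (35.2 to 6.30 kb). Of the 20 housekeeping genes, 2 were longer in MV4-11-MITR (SDHA and TUBB) and none passed the rule in OCI-AML3-MITR.

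Markers of other lineages were followed too. Of 20 T and NK cell markers, 8 were longer and 1 shorter in MV4-11-MITR (percentile 76.3), with TBX21 at 0 and 12.3 kb and CD247 at 0 and 8.41 kb. In OCI-AML3-MITR none was longer and 6 were shorter (10 without scaling), with NCAM1, encoding CD56, at 102 and 13.4 kb, BCL11B at 11.0 and 0.454 kb and CD3E at 9.37 and 0.334 kb. That median lay below those of all 10000 matched random lists. Random lists draw scattered genes and make no allowance for neighbours such as CD3D, CD3E and CD3G. The rank can therefore overstate how far the list stands out. Of 20 B cell markers, 4 were longer and 3 shorter in MV4-11-MITR (3 and 3 without scaling; percentile 99.1), and 1 longer and 4 shorter in OCI-AML3-MITR (0 and 5 without scaling; percentile 4.23), with PAX5 at 10.9 and 0.229 kb and POU2AF1 at 6.33 and 0 kb. Of 20 erythroid and megakaryocyte markers, 3 were longer and none shorter in MV4-11-MITR (3 and 1 without scaling), with GATA1 at 2.87 and 13.0 kb. In OCI-AML3-MITR 3 were longer and 1 shorter (0 and 2 without scaling). Of 20 epithelial and neural markers, 5 were longer and 1 shorter in MV4-11-MITR, with KRT19 at 0 and 7.51 kb, and 1 longer and 2 shorter in OCI-AML3-MITR. The medians of the last 2 lists equalled the value of a gene with no peak in both lines and lay near the middle of random lists (percentiles 49.4 and 50.7, and 46.8 and 50.3). Among the calls named above, HOXB2, HOXB9, BICRA and RIGI in OCI-AML3-MITR and MED1, EED, CEBPB, GATA2, RIGI, REL and HLA-DPA1 in MV4-11-MITR lay inside the rule under 2 of 5 other settings. Under 1 of 5 so did BAK1, BBC3, CD247, FPR2, GSK3B, HOXB2, LTF, MLLT3, STAT5A and TUBB in MV4-11-MITR and CCL20, CDK4, CSF2RB, FPR2, FZD1, GATA2, KIT, KLF2, LYZ, MMP8, PIM1, POU2AF1 and SMARCD1 in OCI-AML3-MITR.

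**Figure D4:**
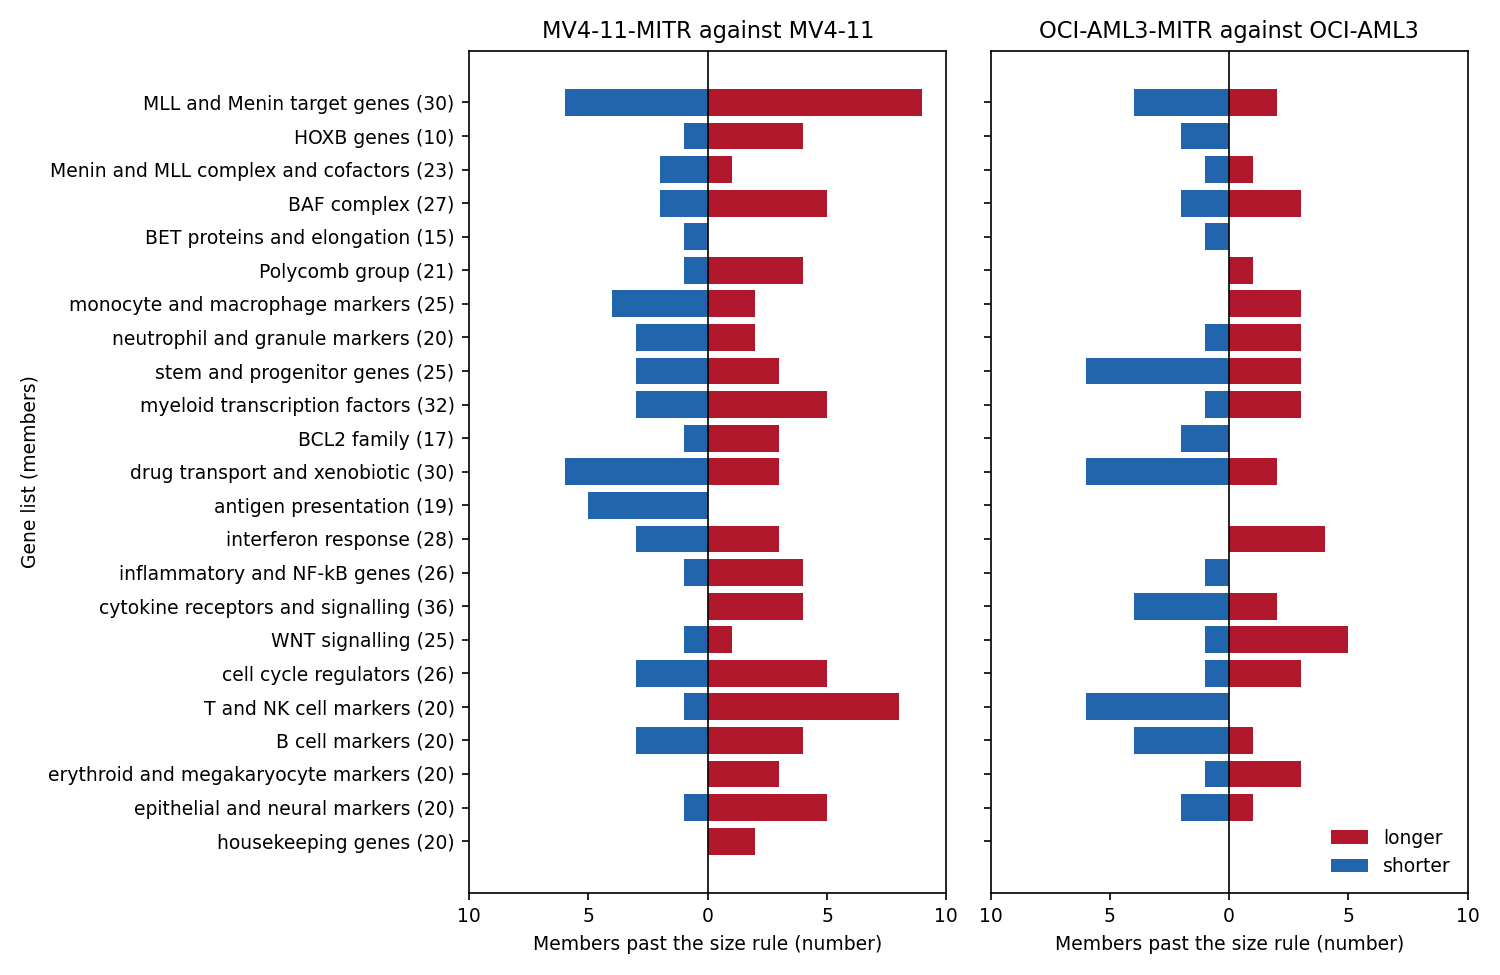
Number of members of each of 23 gene lists (list size in brackets) whose acetylated length was longer (right, red) or shorter (left, blue) by the size rule, in each MITR line against its parent. In OCI-AML3-MITR the T and NK cell list has 6 shorter and no longer members, and in MV4-11-MITR the MLL and Menin target list has 9 longer and 6 shorter.

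Over all 19970 protein-coding genes, 2965 were longer and 2021 shorter in MV4-11-MITR (2676 and 2274 without scaling), and 1488 were longer and 1199 shorter in OCI-AML3-MITR (563 and 2119 without scaling). Scaling by total covered length shifts every gene by 0.10 and 0.42 on the log2 scale, the value of a gene with no peak in either list. Longer in both lines were 367 genes and shorter in both 180, while 204 were longer in MV4-11-MITR and shorter in OCI-AML3-MITR and 221 the other way. Among the 14968 genes with a peak in both pairs independent lists would give 213.4, 116.5, 169.6 and 146.7, so same and opposite changes both lay above independence and the excess is no measure of a shared response. Acetylated length in MV4-11-MITR lay more on gene-dense chromosomes, with scaled log2 changes of 0.46 on chromosome 19 and 0.41 on chromosome 22 against −0.36 on chromosome 18 and −0.28 on chromosome 4, though chromosome 11, with more genes per Mb than chromosome 22, changed by −0.13. In OCI-AML3-MITR chromosome 19 changed by 0.33 and chromosome 18 by −0.21.

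Promoter marks asked which genes switched between a marked and an unmarked state. In MV4-11-MITR 1336 genes gained a mark and 674 lost one, of which 527 and 295 had no peak of the other list within 10 kb. At −log10 q of at least 5 the numbers were 1086 and 1099, so the excess of gains was gone. Strand was not given, so a peak named here or for OCI-AML3-MITR below can lie at the 3′ end of its gene. The strongest gained peak lay over the lower-coordinate end of MYT1L, a neural zinc finger gene (chromosome 2, gene 1789113 to 2331275, peak 1780831 to 1840733, authors' fold enrichment 12.5). DHRS3, a retinol metabolism gene, followed (chromosome 1, peak 12536409 to 12631731, fold 7.39). The next were TBC1D28, SPATS2L, LSM6, ACTR3B, TMCC2, ZIM3, PCDHB1 and MSRB3, at folds of 4.35 to 3.71. The strongest lost peaks lay at KCNK10, a potassium channel gene (chromosome 14, peak 88250142 to 88326880, fold 6.52), NETO2 (fold 5.96) and CSMD3 (fold 4.80), followed by CTXN2 with MYEF2, ARHGAP21, ST8SIA6, FCGR1A, SLC24A5, CD276 and TMCO4. When 500 bp of the window had to be covered, TBC1D28, SPATS2L, LSM6, ACTR3B, TMCC2 and FCGR1A were no longer called. TBC1D28, PCDHB1 and FCGR1A have close paralogs, so reads there may be misplaced.

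In OCI-AML3-MITR 543 genes gained a promoter mark and 626 lost one, 207 and 220 with no peak of the other list within 10 kb. The strongest lost peaks lay at LHX2, a LIM homeobox gene (chromosome 9, peak 123996125 to 124023219, fold 11.3), and MEIS1 (chromosome 2, peak 66431972 to 66453495, fold 10.5). Further losses were at KRTAP7-1, ZNF649, USP28, MPZL2, TESC, MAB21L4, KLHL29 and SEPTIN10 with SOWAHC, at folds of 4.51 to 2.89. The strongest gained peaks lay at DPEP1, a dipeptidase gene (chromosome 16, peak 89613029 to 89618884, fold 6.63), DACH1, a transcriptional cofactor gene (fold 5.39), and PTPRK, a receptor phosphatase gene (fold 5.12). KBTBD8, EFL1 with SAXO2, PAPSS1, ANKRD36B, CCDC62, OSCP1 and ICA1L followed at 4.35 to 3.78. With 500 bp of the window covered, EFL1, ANKRD36B and CCDC62 were no longer called. In the equal-length lists the balance became 1108 gained and 222 lost. Gains also outnumbered losses with equal numbers of peaks (574 and 520), at −log10 q of at least 5 (642 and 445) and with 500 bp covered (619 and 586). Under the remaining settings losses stayed in excess.

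Both lines gained 83 promoters, against 35.7 for independent lists, and both lost 42, against 12.4. At −log10 q of at least 5 the first number was 46, and with equal covered length the second was 9. Under the 10 kb rule 15 genes were gained in both, led by CDC42BPB, a kinase gene, LY96, encoding a cofactor of the endotoxin receptor, HERC5, an interferon-induced ligase gene, SAT2, PRKAG3, ADAMTS6, SPRYD3, EFNA4, DDT with DDTL, and HIVEP3. The lost genes numbered 5 (ZNF649, FSBP, HTR1F, OR52K1 and OGDHL). Genes gained in MV4-11-MITR and lost in OCI-AML3-MITR numbered 71, against 112.0, and those lost and gained 42, against 42.8. In the MV4-11 and OCI-AML3 pairs the authors' folds were 2.71 and 3.08 at CDC42BPB and 2.79 and 4.37 at ZNF649. Independent lists make no allowance for genes that lie near the calling limit in both parents, so the excess is no measure of a shared response.

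Distal regions lay more than 2 kb from every gene end. They were counted per peak and promoters per gene, so the 2 rates of change cannot be compared. MV4-11-MITR gained 18242 of its 43425 distal peaks (42.0%, 17.8 Mb) and lost 17398 of the 38272 of MV4-11 (45.5%, 19.3 Mb). OCI-AML3-MITR gained 16483 of 49793 (33.1%, 9.80 Mb) and lost 32345 of the 57576 of OCI-AML3 (56.2%, 28.1 Mb). These regions were narrow, with median widths of 624, 676, 432 and 579 bp, and their median authors' folds were 2.25, 2.35, 2.23 and 1.97. Of the regions gained in MV4-11-MITR, 507 (2.78%) touched a region gained in OCI-AML3-MITR, against 4.38% of all its distal peaks, and of those lost 1663 (9.56%) touched a lost one, against 13.3%. All distal peaks include the changed regions themselves, and peak width, on which contact depends, was not matched. The lower shares are therefore no measure of overlap between the lines. At −log10 q of at least 5 the counts fell to 1145 gained and 1811 lost in MV4-11-MITR and 998 and 1789 in OCI-AML3-MITR. In lists of equal covered length they were 4836 gained and 1717 lost in MV4-11-MITR and 29940 and 2287 in OCI-AML3-MITR, so the excess of losses in OCI-AML3-MITR turned. It held with equal numbers of peaks (12559 gained and 18958 lost), a setting under which MV4-11-MITR had more losses than gains (13871 and 18423).

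Among the 500 strongest stitched domains of each list, 64.4% of those of MV4-11-MITR (95% Wilson interval 60.1 to 68.5) overlapped one of MV4-11, and 70.8% of those of OCI-AML3-MITR (66.7 to 74.6) one of OCI-AML3. Between the parents 52.2% did (47.8 to 56.5). The 5 strongest top domains of MV4-11 that overlapped no top domain of MV4-11-MITR lay at INHBA, encoding an activin subunit, FRY, ZNF438 (190.3 kb covered, against 24.6 kb in the MITR list), GPR160 and LMO2, a leukaemia-associated LIM gene (115.2 against 60.0 kb). The strongest of MV4-11-MITR against MV4-11 included those at HIC1, CEBPB (231.4 against 127.3 kb), VPS13D, whose domain includes the DHRS3 peak (186.4 against 23.2 kb), and ZDHHC14. Those of OCI-AML3 against its MITR list lay at MKX, BCL2 (204.4 against 69.1 kb), INHBA, HOXB4 (85.0 against 36.6 kb) and UACA. Those of OCI-AML3-MITR against OCI-AML3 lay at CD70 (61.6 against 51.0 kb), SEMA6A (86.3 against 58.8 kb), EEF1G (72.3 against 71.4 kb), RPL19 (68.6 against 44.3 kb) and MAN2A2 (83.2 against 53.0 kb). A domain can thus leave the top 500 of the other list by rank while nearly all of its length is covered there, as at EEF1G. A top domain lay on MEIS1 in both parents and in neither MITR line, and on MEF2C in MV4-11 and not in MV4-11-MITR. Top domains on CDK6, MYB and SPI1 were present in all 4 lists, and HOXA9 had one in MV4-11-MITR, OCI-AML3 and OCI-AML3-MITR.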

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

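The following results went opposite ways in the MV4-11 and OCI-AML3 pairs. With 1 library per line these differences were not tested. The number of peaks, as the ratio of MITR to parent, was 1.29 times as high in the MV4-11 pair as in the OCI-AML3 pair, but at −log10 q of at least 5 the log2 ratios were −0.049 and −0.038, the same way in both. Among list members past the size rule with opposite signs, the scaled log2 change in MV4-11-MITR minus that in OCI-AML3-MITR was 6.28 for HOXB2, 4.57 for CDKN2C, 3.67 for CCL20, 3.60 for SLC4A1, the erythrocyte anion exchanger gene, and 3.05 for ABCG2, a drug efflux pump gene. It was −2.85 for FPR2, −3.65 for CYP3A5, a drug-metabolizing enzyme gene, and −5.33 for ABCC5, another transporter gene. ABCG2 in MV4-11-MITR lay inside the size rule under 5 of 5 other settings, and ABCC5 in OCI-AML3-MITR under 4 of 5. Of the others only CDKN2C passed the rule in both lines under all 5.

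The tests weighed below were stated before their results were seen, except that of MEIS1 in OCI-AML3-MITR alone, which was chosen after.

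The first pattern is the shift of acetylated length in MV4-11-MITR towards gene-dense chromosomes. A change in the copy number of whole chromosomes would leave no such trend within chromosomes, but over 1 Mb bins the median within-chromosome Spearman rho between change and gene density was 0.31, positive on 23 of 23 chromosomes. A preference of the whole library for gene-dense, GC-rich DNA would show in distal peaks too, and there the median rho was 0.30, so it stays open. In OCI-AML3-MITR the values were 0.13 and 0.02. A difference in chromatin between the MV4-11 lines is also open and untested, and changes of gene-dense or gene-poor loci in MV4-11-MITR should be read against this trend.

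The second pattern is the loss of acetylated length at MEIS1 in both MITR lines. Loss of all copies of the whole segment is argued against by the 1 Mb flanks, where the lower ratio of acetylated length, MITR over parent, was 0.76. The flanks held little: 17.4 kb in MV4-11-MITR against 20.1 kb in MV4-11, and 18.0 kb in OCI-AML3-MITR against 23.5 kb in OCI-AML3. Peak length need not follow copy number, so loss of only some copies cannot be judged from it. A smaller deletion was not tested. For both lines together the length of the lists and the gene density trend stay open, since the highest of the log2 changes in lists of equal number or length was −0.97 and the higher percentile among matched genes 6.82, both from MV4-11-MITR. In OCI-AML3-MITR alone MEIS1 lay at percentile 0.35 of 287 matched genes. Its lack of any peak there was known when this test was chosen, so the rank decides nothing about the trend. With equal numbers of peaks and with equal covered length the change there was −5.51 and −5.56, so shortening the parent's list did not remove its peaks at MEIS1. The length of the lists is still not settled there, since shortening cannot restore a peak that OCI-AML3-MITR does not hold. A biological difference between the sublines and their parents is also open and untested.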

How the results depend on the processing

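Of 130 values of whole comparisons under other settings, 87 stayed within 1.5 times the reported count or inside the binomial interval of the reported share. The others follow, and where no reason is given the cause was not tested. With equal numbers of peaks the OCI-AML3 pair had a Jaccard index of 0.554 and lost 18958 distal regions, and 0 MLL and Menin targets were longer in OCI-AML3-MITR. With equal covered length the indices were 0.556 (MV4-11 pair) and 0.570 (OCI-AML3 pair), OCI-AML3-MITR gained 1108 promoters and lost 222, and 9 promoters were lost in both lines. Distal regions gained and lost were then 4836 and 1717 in MV4-11-MITR and 29940 and 2287 in OCI-AML3-MITR, so in OCI-AML3-MITR the balance turned from losses to gains. OCI-AML3-MITR keeps its whole list under this rule while the others are shortened. At −log10 q of at least 5 the log2 ratio of peak numbers in the MV4-11 pair turned from 0.19 to −0.049, and the indices were 0.543 and 0.580. Promoters gained and lost in MV4-11-MITR were 1086 and 1099, those gained in both lines 46, and distal regions gained and lost 1145 and 1811 in MV4-11-MITR and 998 and 1789 in OCI-AML3-MITR, from shorter lists.

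With no peak of the other list allowed within 10 kb, promoters gained and lost were 527 and 295 in MV4-11-MITR, 207 and 220 in OCI-AML3-MITR, and 15 and 5 in both lines. With none within 5 kb, distal regions gained and lost were 9485 and 8694, and 6050 and 16514. Overlap of the top 1000 domains was 69.2% in MV4-11-MITR and 76.5% in OCI-AML3-MITR, and without peaks near gene ends 59.4% in MV4-11-MITR. With a pseudo-length of 2000 bp 1230 genes were shorter in MV4-11-MITR, and 749 longer and 578 shorter in OCI-AML3-MITR. Without scaling 563 were longer and 2119 shorter there. The longer MLL and Menin targets of OCI-AML3-MITR numbered 0 with this pseudo-length, with flanks of 5 or 50 kb and without scaling.

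For 112 genes named by length, 996 of 1120 values stayed on their side of the size rule. Of the 128 values past the rule, 60 stayed so under all 5 settings, 43 under all but 1, 17 under all but 2 and 8 under fewer. Equal covered length and a −log10 q of at least 5 were not among the 5. MEIS1 in MV4-11-MITR, kept under all 5, changed by −0.97 with equal covered length, inside the rule. With 5 kb flanks CYP3A5 (0.10) and HOXB7 (0.10) in MV4-11-MITR and POU2AF1 (0.42) in OCI-AML3-MITR had no peak left in either list, which gives these values, and MED12 (0.38) in OCI-AML3-MITR had nearly equal lengths. With 50 kb flanks the direction turned for HOXB7 (1.82) and SMARCD1 (−1.01) in MV4-11-MITR and for HOXA2 (−0.083) and SLC4A1 (0.34) in OCI-AML3-MITR. The percentiles of 4 lists in MV4-11-MITR and 6 in OCI-AML3-MITR lay outside the central 95%, 2 of the 6 only by passing the value of a gene with no peak; with gene density matched, a choice made after seeing the data, 3 and 5 did. Lists share members and neighbouring genes, so no number expected by chance is given. Taking only the gene end with more acetylation, also chosen after, kept all promoter counts within 1.5 times. Counts by the 5′ end alone and motif searches were not run. No paired test over both lines was run, each group had 1 library, and no result comes from a test. Depth, unknown here, limits what a missing peak shows.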

Other observations

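Outside the fixed lists, genes that changed the same way in both lines were chosen after their values were seen, by the smaller of their log2 changes among genes with at least 10 kb in the longer lists. On the shorter side 37 genes passed. They were led by ZMAT4, a zinc finger gene (12.7 to 0 kb in MV4-11-MITR and 10.9 to 0 kb in OCI-AML3-MITR), ADGRL2, an adhesion receptor gene (13.8 to 2.07 kb, and 20.2 to 2.86 kb) and PTK2, encoding focal adhesion kinase (16.9 to 3.19 kb, and 16.1 to 0.703 kb). LMO1, a T-cell leukaemia gene related to LMO2, was also among them (10.6 to 0.247 kb, and 10.0 to 1.87 kb). On the longer side 39 passed, led by TMEM120A (3.85 to 23.7 kb, and 4.53 to 10.5 kb), DVL1, a WNT pathway gene (10.9 to 33.6 kb, and 5.22 to 11.8 kb), and NEU4 (2.97 to 13.5 kb, and 4.88 to 10.7 kb). With 50 kb flanks NEU4 in both lines (0.70 and 0.45) and TMEM120A (0.75) and PTK2 (−0.69) in OCI-AML3-MITR lay inside the size rule.

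Within the limits of the HOX clusters HOXC had 12.5 kb in MV4-11, 31.5 kb in MV4-11-MITR, 2.73 kb in OCI-AML3 and 0 in OCI-AML3-MITR. HOXA had 12.9 and 51.4 kb in the MV4-11 pair and 54.9 and 47.7 kb in the OCI-AML3 pair, and HOXD had 0 in all 4 lists.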
